A study of Mus musculus with 28 samples.

How the data were processed

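Gene expression was measured by RNA sequencing of polyadenylated RNA in 16 whole kidney libraries and 12 libraries of sorted kidney macrophages from female C57BL/6 mice of 7 to 9 months. Per the labels' protocols, kidney libraries were made with a TruSeq kit and macrophage libraries with SMART-Seq v4 after collagenase digestion, a Percoll gradient and cell sorting, and all were sequenced as single reads on an Illumina HiSeq instrument. The tissues were normalized separately in the deposited files, so each test was run within a tissue. Groups were taken from the genotype label of each library. The titles of double-mutant libraries name only the Rhbdf2 knockout while their genotype label gives both, and the label was followed. The titles give each library a number or letter of its own, but the labels do not say whether each came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical. In kidney each genotype was run on its own lane, so lane and genotype cannot be told apart and lane could not be a term of the fit.

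Per the file headers, the deposited expression values are log2 CPM computed by the authors for each library. The values themselves show a small prior count and an effective library size, and genes had already been filtered. Per the file headers, the deposited log2 fold changes, p-values and FDR values are the authors' own for 4 comparisons per tissue, and the headings and name of the table point to an edgeR fit. Gene length in bases is also the authors' column and was not used in a test. The builds mm10 and GRCm38 are named in the submitters' processing notes. The aligner, the counting program, the annotation and whether strand was used are not given in the sources used here, so overlapping or antisense genes and near-identical copies, such as the Cyp4a12 pair and the immunoglobulin genes, are uncertain. Gene positions are those of the deposited files. Of genes whose symbol was found in GENCODE vM21, 99.8% in kidney and 99.9% in macrophages overlapped their position there. There were 0 other columns of values per sample, and 0 pairs of libraries held identical values.

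Low values in each library were whole multiples of what 1 read is worth, after removal of the prior count. All low values came out whole in each library (100%, tolerance 0.1 read, 9888 values in kidney and 10741 in macrophages), which gave the number of reads in the listed genes. A read was worth 0.0226 to 0.0354 CPM in kidney and 0.0277 to 0.033 CPM in macrophages. A floor of 3 reads lay at 0.0677 to 0.106 CPM in kidney and 0.0831 to 0.0989 CPM in macrophages, and it covers counting error only.

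The design written before the data were examined foresaw counts, with limma-trend on log2(value+1) as the fallback for normalized values. Since the files hold log2 CPM, the fallback was used. CPM was recovered as the antilog of the deposited value, and log2(CPM+1) was fitted with limma 3.58.1 in R 4.3.3, with all 4 groups of a tissue in the same fit so that they share an estimate of spread. Each comparison is a contrast of 2 group means, and the interaction is double mutant minus Fcgr2b-/- less the difference of Rhbdf2-/- and wild-type. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison, with all deposited genes tested. Fold changes are on the log2(CPM+1) scale, which understates the change of genes with low values. Their SE is that of limma with n = 4 per group in kidney and n = 3 in macrophages. Means of CPM are given with the SD over libraries.

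Named genes followed a rule fixed at the same time. Rhbdf2 and Fcgr2b are always given. For the 3 main comparisons the 8 largest rises and 8 largest falls could be named, and for the other comparisons 3 and 3, among called genes with a mean log2 CPM of at least 1 and no overlap of the groups' values. Predicted genes, clone names and immunoglobulin segments were left out of these rises and falls. Up to 4 members with the smallest p of each list that passed, or that held at least 2 called members, could be added, and Hbegf, Tnf, Egfr, Adam17, Havcr1, Lcn2 and Ccl2 were given whatever their result. Where fewer than 6 genes met the rule, the 6 with the smallest p are given as values. Some genes that met the rule are not reported here. The genes beside Rhbdf2, the sex-biased genes, Umod and the immunoglobulin levels were chosen after their values were seen. Lists of genes for pathways and cell types, 26 in all, were fixed then as well. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and lists with fewer than 3 measured members were not tested. With an estimated correlation 4 of 138 passing list tests held, all in macrophages. They were the lipid and lysosomal, tubular injury and matrix lists in double-mutant against Fcgr2b-/- cells and the tubular injury list in the interaction.

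The procedure was tested on simulated data in which 200 genes were changed in the comparison of Fcgr2b-/- with wild-type. In kidney (12315 genes) 41%, 85.5% and 98.5% of genes changed by a log2 value of 0.5, 1 and 2 were recovered, with 5.75%, 7.57% and 3.9% of calls false. In macrophages (10523 genes) the recovered shares were 0%, 68% and 92.5%, with 0%, 6.21% and 3.65% of calls false.

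Alternatives were a pseudocount of 0.1, a mean CPM of at least 5, median-of-ratios scaling, the 2 compared groups alone, a replicate block for the macrophage letters and leaving out each library in turn. After the data had been seen, voom on the recovered reads, the deposited log2 values without a pseudocount, macrophage genes at least as high as in wild-type kidney, and gene lists without each library in turn were added. The filter was set at 5 because a mean CPM of at least 1 removed no gene. Shared control libraries were handled by simulating groups without effects and by splitting the Fcgr2b-/- kidney libraries. Overlaps and loci were tested with Fisher's exact test, two-sided, within 10 Mb of each targeted gene.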

Results

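RNA sequencing was carried out on whole kidney and on macrophages sorted from kidney in female C57BL/6 mice aged 7 to 9 months. Wild-type mice were set beside mice lacking Rhbdf2, which encodes iRhom2, the inactive rhomboid protein that carries the protease ADAM17 to the cell surface, where it sheds TNF and several ligands of the EGF receptor. A further group lacked Fcgr2b, the inhibitory receptor for IgG whose loss leads to lupus-like autoimmunity with nephritis on this background, and the last group lacked both genes and is called double mutant here. The kidney set held 16 libraries, 4 per genotype. The macrophage set held 12 libraries, 3 per genotype, from cells carrying CD45, F4/80 at a high level and CD11b but neither Ly6G nor Ly6C. Reads recovered from the deposited values ranged from 29016105 to 41620058 per kidney library and from 30850363 to 34871547 per macrophage library. The deposited values covered 12315 genes in kidney and 10523 in macrophages. Fold changes are log2 ratios with their standard error.

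The targeted genes were examined first. In mm10, Rhbdf2 lies on chromosome 11 from 116598164 to 116627019 and Fcgr2b on chromosome 1 from 170960557 to 170976547, both on the minus strand, and each value counts reads over a whole gene. Kidney Rhbdf2 was 12.9 CPM in each wild-type library, 10.8 to 12.3 in Rhbdf2-/-, 25 to 37.1 in Fcgr2b-/- and 9.29 to 19.7 in double mutants. Kidney Fcgr2b ranged from 29.3 to 35.8 CPM in wild-type, 31.7 to 35.3 in Rhbdf2-/-, 23.4 to 34.2 in Fcgr2b-/- and 20.7 to 41.5 in double-mutant libraries. In macrophages Rhbdf2 ranged from 16.2 to 25 CPM in wild-type, 13.4 to 15.5 in Rhbdf2-/-, 25.2 to 43.3 in Fcgr2b-/- and 18.1 to 26.6 in double-mutant libraries. Macrophage Fcgr2b ranged from 539 to 715 CPM in wild-type, 612 to 715 in Rhbdf2-/-, 256 to 382 in Fcgr2b-/- and 455 to 550 in double-mutant libraries. Reads of both genes were thus present in the libraries labelled as lacking them. Which part of each gene was deleted is not given in the sources used here, so reads outside the deleted part may make up these values and they do not check the labels.

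The comparison of Fcgr2b-/- with wild-type kidney addressed which transcripts accompany nephritis after loss of the inhibitory Fc receptor. Lcn2, which encodes the secreted injury marker NGAL, averaged 458 ± 299 CPM (SD, n = 4) in Fcgr2b-/- kidney against 2.99 ± 1.63 in wild-type, a log2 change of 6.73 ± 0.62 (SE; limma adjusted p = 8.48e-07). Havcr1, which encodes the tubular injury molecule KIM-1, averaged 161 ± 111 against 0.961 ± 0.814 CPM and rose by 6.16 ± 0.71. Serpina3n, an acute-phase protease inhibitor, rose by 4.89 ± 0.44 and Ltbp2, a matrix protein related to fibrillins, by 4.71 ± 0.48. Genes of the healthy tubule fell, among them Kap, an abundant transcript of proximal tubule cells, which changed by -4.85 ± 0.30 from 7582 ± 1210 to 279 ± 133 CPM. Pvalb, a calcium-binding protein of the early distal convoluted tubule, changed by -5.05 ± 0.44, the secreted nuclease Dnase1 by -4.69 ± 0.43 and Egf, the growth factor precursor made in distal tubule, by -2.74 ± 0.24.

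**Figure D1:**
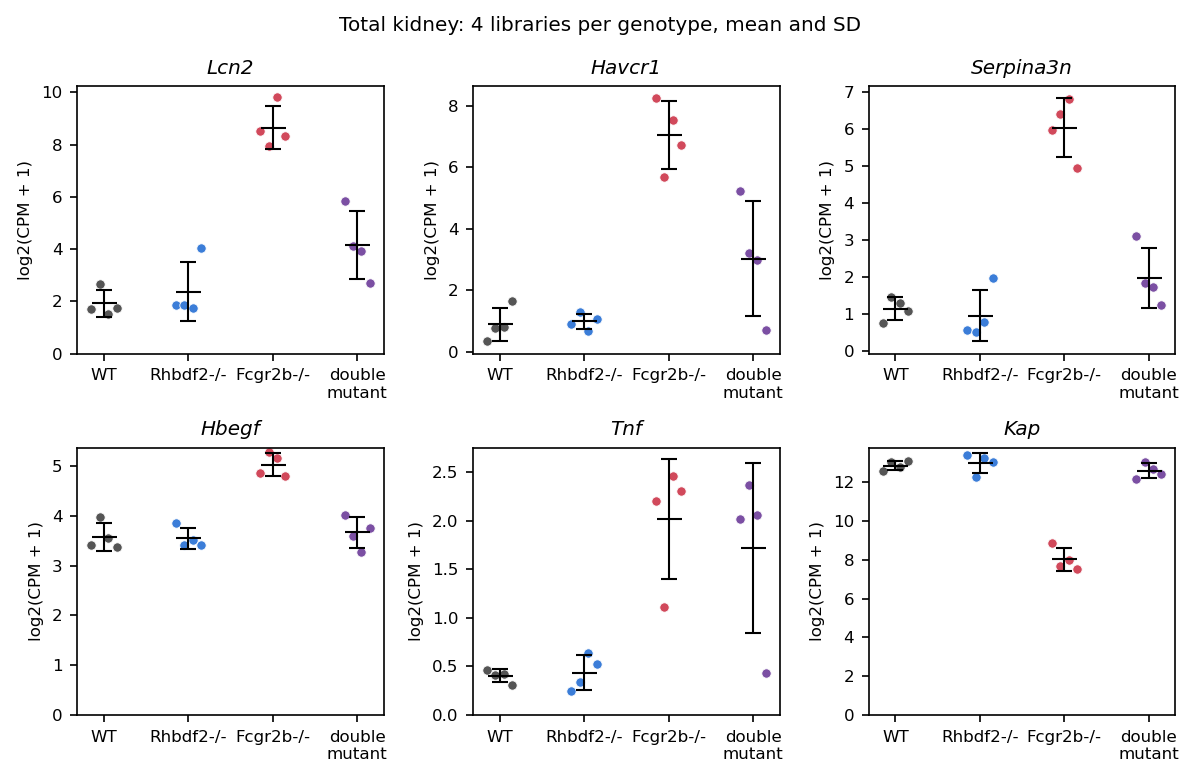
Expression of 6 genes in whole kidney as log2(CPM+1), with 1 point per library, the 4 genotypes on the horizontal axis, and bars at the mean with its SD (n = 4). Lcn2, Havcr1, Serpina3n and Hbegf were highest in Fcgr2b-/- libraries, Kap was lowest there, and Tnf averaged 3.3 CPM in Fcgr2b-/- and 2.68 CPM in double-mutant kidney against 0.324 CPM in wild-type.

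Every measured member of the tubular injury list, 22 of 22, rose in Fcgr2b-/- kidney over all genes and also adjusted over the list alone, with a median log2 change of 2.24 (camera adjusted p = 4.96e-12, adjusted p = 0.248 with an estimated correlation). Among TNF and NF-kB response genes 24 of 28 rose (25 over the list alone, median 1.63, camera adjusted p = 3.4e-09, adjusted p = 0.42 with an estimated correlation). Members included Cxcl1, a neutrophil-attracting chemokine, at 3.19 ± 0.20, Socs3, a feedback inhibitor of cytokine receptors, at 3.38 ± 0.26 and the leukocyte adhesion molecule Vcam1 at 3.16 ± 0.39. Of the early response genes of EGFR and ERK signalling 14 of 16 rose (14 over the list alone, median 0.79, camera adjusted p = 2.71e-05, adjusted p = 0.413 with an estimated correlation). Among them were the transcription factors Egr1 (3.02 ± 0.34), Fos (2.78 ± 0.33), Myc (2.15 ± 0.22) and Etv4 (1.67 ± 0.18). The list of handling stress genes, which shares Egr1 and Fos with it, rose in 10 of 18 cases and fell in 5 (the same counts over the list alone, median 1.20, camera adjusted p = 0.0146). Matrix genes rose in 24 of 26 cases (24 over the list alone, median 1.88, camera adjusted p = 5.58e-08, both adjusted p = 0.42 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, stood at 4.13 ± 0.37, the collagen cross-linking enzyme Lox at 3.31 ± 0.35 and smooth-muscle actin, Acta2, at 1.77 ± 0.21. The proximal tubule list fell in 19 of 21 members and rose in 0 (19 over the list alone, median -1.27, camera adjusted p = 4.73e-07, adjusted p = 0.42 with an estimated correlation). Among them Gatm, a creatine-synthesis enzyme, stood at -2.51 ± 0.22.

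Macrophage markers moved with these groups. They rose in 18 of 20 cases and fell in 1 (the same counts over the list alone, median 2.64, camera adjusted p = 1.81e-06, adjusted p = 0.42 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, rose by 4.07 ± 0.54, Gpnmb, a glycoprotein of lysosome-rich macrophages, by 4.24 ± 0.49 and the complement component C1qa by 2.95 ± 0.41. Complement genes rose in 12 of 16 cases (13 over the list alone, camera adjusted p = 0.000149). Proliferation genes rose in 17 of 18 cases, with 1 fall (the same counts over the list alone, camera adjusted p = 4.64e-05, both adjusted p = 0.42 with an estimated correlation). Interferon-stimulated genes rose in 18 of 29 cases and fell in 3 (20 and 3 over the list alone, median 0.95, camera adjusted p = 0.00544, adjusted p = 0.656 with an estimated correlation). MHC class II genes rose in 7 of 9 cases (7 over the list alone, median 1.75), while the list test gave a camera adjusted p of 0.0602. The tests of 3 further leukocyte lists did not pass either, with 1 of 13 B and plasma cell genes higher (1 over the list alone, median 1.42, camera adjusted p = 0.073), 3 of 10 T and NK cell genes (1 over the list alone, median 0.87, camera adjusted p = 0.0908) and 2 of 6 dendritic cell genes (2 over the list alone, median 0.44, camera adjusted p = 0.149). The MHC class II list passed without iR2ko_65 (camera adjusted p = 0.0123), iR2ko_367 (0.0202) or WT_388 (0.0478), the T and NK list without iR2ko_65 (0.0394) and the B and plasma list without FcR2bko_594 (0.00666), FcR2bko_591 (0.0461) or WT_388 (0.0488).

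The genes of the iRhom2 pathway were followed in each comparison. In Fcgr2b-/- kidney Hbegf, an EGFR ligand shed by ADAM17, rose by 1.45 ± 0.17 (SE, n = 4 per group; limma adjusted p = 6.85e-06), from 11.1 ± 2.47 to 31.9 ± 5.25 CPM (SD). Tnf rose by 1.62 ± 0.36 (adjusted p = 0.00137), Rhbdf2 by 1.26 ± 0.17 and Adam17 by 0.36 ± 0.10 (adjusted p = 0.00718). Timp3, an inhibitor of ADAM17, changed by -1.47 ± 0.16. Egfr had a log2 change of -0.15 (adjusted p = 0.232) and Fcgr2b itself -0.20 (adjusted p = 0.333), neither past the threshold. The list of iRhom2 and ADAM17 components and shed substrates rose in 14 of 18 members and fell in 2 (the same counts over the list alone, median 0.90, camera adjusted p = 0.00179, adjusted p = 0.42 with an estimated correlation). Of 10 genes of the EGFR ligand and receptor list 2 rose and 3 fell (2 and 3 over the list alone, median -0.06, camera adjusted p = 0.779).

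In all, 7422 of 12315 kidney genes changed between Fcgr2b-/- and wild-type mice (limma, adjusted p below 0.05), 3627 higher and 3795 lower. By the authors' deposited table the count was 7405, and 7274 genes were shared with the same sign. Genotype could not be told apart from sequencing lane in kidney, since each genotype was run on 1 lane. Mitochondrial transcripts took 10.4 to 11.8% of wild-type reads and 5.87, 6.73, 9.06 and 14.5% in the Fcgr2b-/- libraries, the last in library FcR2bko_594.

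The comparison of double-mutant with Fcgr2b-/- kidney addressed what loss of iRhom2 changes when Fcgr2b is absent. Lcn2 averaged 23.2 ± 23 CPM (SD, n = 4) in double mutants against 458 ± 299 in Fcgr2b-/- kidney, a log2 change of -4.51 ± 0.62 (SE; limma adjusted p = 6.24e-05). Havcr1 changed by -4.02 ± 0.71, Serpina3n by -4.06 ± 0.44 and Cxcl1 by -2.77 ± 0.20. Kap rose by 4.57 ± 0.30 to 6354 ± 1730 CPM, Pvalb by 3.12 ± 0.44 and Egf by 2.33 ± 0.24. Hbegf changed by -1.36 ± 0.17 (adjusted p = 3.1e-05), to 11.9 ± 2.76 CPM. Tnf did not pass the test, at -0.30 ± 0.36 (adjusted p = 0.513), with 2.68 ± 1.63 CPM in double mutants and 3.3 ± 1.48 in Fcgr2b-/- kidney.

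Of 22 tubular injury genes 20 fell in the double mutant (21 over the list alone, median -2.12, camera adjusted p = 6.72e-13, adjusted p = 0.202 with an estimated correlation). Matrix genes fell in 20 of 26 cases (23 over the list alone, median -1.40, camera adjusted p = 2.2e-07, adjusted p = 0.704 with an estimated correlation). Timp1 stood at -3.06 ± 0.37 and Acta2 at -1.97 ± 0.21. EGFR and ERK early genes fell in 12 of 16 cases (12 over the list alone, median -0.78, camera adjusted p = 2.13e-05, adjusted p = 0.462 with an estimated correlation). Etv4 changed by -1.70 ± 0.18, Myc by -1.76 ± 0.22 and Spry4, an inhibitor of receptor tyrosine kinase signalling, by -0.79 ± 0.10. Handling stress genes fell in 9 of 18 cases and rose in 2 (the same counts over the list alone, median -0.70, camera adjusted p = 0.0102, adjusted p = 0.704 with an estimated correlation). TNF and NF-kB response genes fell in 16 of 28 cases (17 over the list alone, median -0.73, camera adjusted p = 0.000394, adjusted p = 0.788 with an estimated correlation). Proximal tubule genes rose in 16 of 21 cases (17 over the list alone, median 0.83, camera adjusted p = 1.52e-05, adjusted p = 0.704 with an estimated correlation).

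Interferon-stimulated genes moved the other way, with 10 of 29 higher in the double mutant and 0 lower (10 over the list alone, median 0.59, camera adjusted p = 0.00264, adjusted p = 0.788 with an estimated correlation). Among them Cmpk2, a mitochondrial nucleotide kinase induced by interferon, rose by 1.04 ± 0.17 and Gbp3, an interferon-induced GTPase, by 2.10 ± 0.46. Double-mutant library iR2ko_65 stood apart, with a mean log2(CPM+1) over the interferon list of 3.81 against 5.03 to 5.37 in the other double mutants and 3.57 to 4.70 in Fcgr2b-/- libraries. Without iR2ko_65 21 of 29 interferon genes rose (24 over the list alone, median 0.93). Macrophage markers fell in 4 of 20 cases (1 over the list alone, median -0.64, camera adjusted p = 0.0936), and the list test passed without FcR2bko_398 (0.0334), iR2ko_370 (0.0233) or iR2ko_367 (0.0204). With all libraries neither MHC class II nor T and NK cell genes held a gene past the threshold, while without iR2ko_65 9 of 9 and 9 of 10 rose (9 and 9 over the list alone, camera adjusted p = 0.00292 and 0.00275). Of iRhom2 and ADAM17 genes 7 fell and 1 rose among 18 (10 and 2 over the list alone, median -0.41, camera adjusted p = 0.041, adjusted p = 0.788 with an estimated correlation), and that test did not pass without iR2ko_65 (0.0868), FcR2bko_21 (0.121) or FcR2bko_591 (0.0867). Rhbdf2 changed by -1.04 ± 0.17, its paralogue Rhbdf1 by -0.75 ± 0.10 and Frmd8, which stabilises iRhom proteins at the cell surface, by -0.47 ± 0.09. Adam17 had a log2 change of -0.09 (adjusted p = 0.501) and Egfr of -0.14 (adjusted p = 0.304).

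Between double-mutant and Fcgr2b-/- kidney 5578 genes changed, 2769 higher and 2809 lower, while the authors' deposited table gave 5488, with 5393 shared. A fit on these 2 groups alone gave 3550. Double-mutant library iR2ko_65 stood apart from the other double mutants, with Havcr1 at 0.629 CPM against 6.87 to 36.8, Lcn2 at 5.51 against 14.2 to 57, Lyz2 at 79.3 against 340 to 644 and a mitochondrial share of 14.3% against 9.19 to 9.73%.

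Loss of Rhbdf2 alone was examined by comparing Rhbdf2-/- with wild-type kidney. No gene passed the threshold. Among the 6 genes with the smallest p-values were 1810041L15Rik (-0.66 ± 0.15; SE, n = 4 per group), Acmsd, an enzyme of tryptophan breakdown (-0.54 ± 0.14), Depdc1b (-0.48 ± 0.10), coagulation factor F5 (-0.66 ± 0.16) and the oxysterol-binding protein gene Osbpl3 (-0.25 ± 0.06), each with a limma adjusted p of 1. Rhbdf2 had a log2 change of -0.13 ± 0.17, Hbegf of -0.03 ± 0.17 and Tnf of 0.03 ± 0.36. The limma count was 0, with 272 genes at an unadjusted p below 0.05 where 616 would be expected by chance, and voom on recovered reads and the authors' deposited table also gave 0. Interferon-stimulated genes had a median of 0.34 (camera adjusted p = 4.72e-07). Macrophage markers had a median of 0.31 (camera adjusted p = 0.0076) and matrix genes a median of -0.30 (camera adjusted p = 0.000441, all 3 adjusted p = 0.988 with an estimated correlation). The EGFR ligand and receptor list had a median of -0.12 (camera adjusted p = 0.022, adjusted p = 0.331 with an estimated correlation) and handling stress genes a median of 0.15 (camera adjusted p = 0.00482, adjusted p = 0.988 with an estimated correlation). In each of these lists 0 genes passed, both over all genes and over the list alone. The macrophage test did not pass without iR2ko_352 (0.14) or iR2ko_355 (0.194), the EGFR test without WT_356 (0.165), iR2ko_352 (0.101) or FcR2bko_591 (0.0558), and the handling stress test without WT_388 (0.236), WT_550 (0.0675) or iR2ko_334 (0.114).

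The effect of Fcgr2b loss in mice already lacking iRhom2 was read from double-mutant against Rhbdf2-/- kidney. Pigr, the receptor that carries polymeric immunoglobulin across epithelia, rose by 2.71 ± 0.51 (SE, n = 4 per group; limma adjusted p = 0.0215), Lyz2 by 2.66 ± 0.54 (adjusted p = 0.0253) and Ms4a6d, a membrane protein of macrophages, by 2.36 ± 0.37. Slc16a14, a member of the monocarboxylate transporter family, changed by -2.26 ± 0.34, Pvalb by -1.85 ± 0.44 and Gldc, of the glycine cleavage system, by -1.40 ± 0.33. Macrophage markers rose in 14 of 20 cases (18 over the list alone, median 1.76, camera adjusted p = 8.88e-14). Interferon-stimulated genes rose in 9 of 29 cases (26 over the list alone, median 1.15, camera adjusted p = 1.57e-18, both adjusted p = 0.254 with an estimated correlation). TNF and NF-kB response genes rose in 11 of 28 cases (25 over the list alone, median 0.98, camera adjusted p = 6.28e-17), Socs3 at 1.60 ± 0.26 and Vcam1 at 2.20 ± 0.39. T and NK cell genes rose in 2 of 10 cases (10 over the list alone, median 1.46, camera adjusted p = 2.6e-07, both adjusted p = 0.254 with an estimated correlation). In iR2ko_65 the means of the macrophage, interferon, TNF and T and NK lists (4.52, 3.81, 2.87 and 1.26) lay within the range of the Rhbdf2-/- libraries. Called members numbered 17, 26, 25 and 10 without iR2ko_65 (18, 28, 26 and 10 over the list alone) and 0, 0, 1 and 0 without Rhbdf2-/- library iR2ko_334 (18, 24, 22 and 7). All 4 list tests passed whichever library was left out. Tnf (1.28 ± 0.36; adjusted p = 0.058), Lcn2 (1.78 ± 0.62; adjusted p = 0.106), Havcr1 (2.05 ± 0.71; adjusted p = 0.105) and Hbegf (0.12; adjusted p = 0.708) did not pass. In total 431 genes changed, 286 higher and 145 lower, while median-of-ratios scaling gave 288 higher and 85 lower and the 2 groups alone 164 higher and 238 lower. The count was 77 with voom on recovered reads, 42 higher and 35 lower, and it ranged from 27 to 1566 when single libraries were left out, 1566 without iR2ko_65.

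Double-mutant kidney was also compared with wild-type to show what remained different in the absence of both genes. Iigp1, an interferon-inducible GTPase, rose by 3.67 ± 0.83 (SE, n = 4 per group; limma adjusted p = 0.0206), Pigr by 2.97 ± 0.51 and Lyz2 by 2.83 ± 0.54. Pvalb changed by -1.93 ± 0.44, Slc16a14 by -1.71 ± 0.34 and the carboxylesterase Ces2b by -1.40 ± 0.41. Interferon-stimulated genes rose in 25 of 29 cases (27 over the list alone, median 1.48, camera adjusted p = 2.13e-25, adjusted p = 0.22 with an estimated correlation). Ifit1, which binds foreign RNA, stood at 2.04 ± 0.32 and Irf7, a transcription factor of the interferon response, at 2.10 ± 0.38. Macrophage markers rose in 17 of 20 cases (18 over the list alone, median 2.19, camera adjusted p = 1.19e-16, adjusted p = 0.22 with an estimated correlation). MHC class II genes rose in 7 of 9 cases (8 over the list alone, median 2.19, camera adjusted p = 4.6e-08). T and NK cell genes rose in 5 of 10 cases (10 over the list alone, median 1.70, camera adjusted p = 2.23e-08, both adjusted p = 0.244 with an estimated correlation). Examples were the protease Ctss at 2.56 ± 0.43 and the MHC class II chain H2-Ab1 at 2.42 ± 0.58. The mean in iR2ko_65 was 4.64 for MHC class II genes, against 4.41 to 4.85 in wild-type and 6.27 to 8.36 in the other double mutants, and 1.26 for T and NK cell genes, against 0.99 to 1.35 and 2.55 to 4.17. Called interferon, macrophage, MHC class II and T and NK members numbered 27, 18, 8 and 10 without iR2ko_65 (29, 18, 9 and 10 over the list alone) and 9, 8, 0 and 0 without WT_346 (27, 18, 8 and 10), and each list test passed in every such fit.

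TNF and NF-kB response genes rose in 14 of 28 cases in double-mutant against wild-type kidney (23 over the list alone, median 0.94, camera adjusted p = 1.19e-16, adjusted p = 0.22 with an estimated correlation). Tnf rose by 1.31 ± 0.36 (SE, n = 4 per group; limma adjusted p = 0.0406) and Lcn2 by 2.23 ± 0.62 (adjusted p = 0.0442). Havcr1 had a log2 change of 2.15 ± 0.71 (adjusted p = 0.0815), Hbegf of 0.09 (adjusted p = 0.797) and Egfr of -0.29 (adjusted p = 0.112), none past the threshold. Tubular injury genes rose in 6 of 22 cases (9 over the list alone, median 0.45, camera adjusted p = 8.42e-05, adjusted p = 0.282 with an estimated correlation). Proximal tubule genes fell in 3 of 21 (7 over the list alone, median -0.44, camera adjusted p = 2.34e-05, adjusted p = 0.328 with an estimated correlation). For the TNF and injury lists iR2ko_65 also lay within the wild-type range, at means of 2.87 and 4.16. Called TNF, injury and proximal tubule members numbered 24, 9 and 6 without it (25, 12 and 9 over the list alone) and 3, 2 and 0 without WT_346 (23, 6 and 1). In total 898 genes changed, 557 higher and 341 lower, while the 2 groups alone gave 416 higher and 672 lower. The authors' deposited table gave 1126, with 889 shared. The count was 479 with voom on recovered reads, 237 higher and 242 lower, and 121 to 1706 with single libraries left out, 1706 without iR2ko_65 and 121 without WT_346.

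Whether Rhbdf2 loss had a different effect with and without Fcgr2b was tested directly as an interaction in kidney. The effect of Rhbdf2 loss on Lcn2 was lower by -4.95 ± 0.88 (SE, n = 4 per group; limma adjusted p = 0.00123) in Fcgr2b-/- than in Fcgr2b-sufficient mice, on Havcr1 by -4.11 ± 1.01 (adjusted p = 0.0081), on Serpina3n by -3.87 ± 0.62 and on Hbegf by -1.33 ± 0.24 (adjusted p = 0.00142). It was higher for Kap by 4.44 ± 0.43 and for Dnase1 by 4.49 ± 0.60. For Rhbdf2 the difference was -0.90 ± 0.24 (adjusted p = 0.0136), and for Tnf it was -0.33 (adjusted p = 0.653), not past the threshold. Of the tubular injury list 18 of 22 genes had a negative interaction (19 over the list alone, median -1.94, camera adjusted p = 4.6e-13, adjusted p = 0.195 with an estimated correlation). Of the EGFR and ERK early list 11 of 16 genes had a negative interaction (12 over the list alone, median -0.78, camera adjusted p = 4.17e-05, adjusted p = 0.526 with an estimated correlation), as did 8 of 28 TNF and NF-kB response genes (9 over the list alone, median -0.70, camera adjusted p = 0.000638, adjusted p = 0.799 with an estimated correlation). Handling stress genes had a negative interaction in 9 of 18 cases and a positive one in 0 (9 over the list alone, median -0.84, camera adjusted p = 0.00127, adjusted p = 0.637 with an estimated correlation). Proximal tubule genes had a positive interaction in 9 of 21 cases (13 over the list alone, median 0.81, camera adjusted p = 4.17e-05, adjusted p = 0.799 with an estimated correlation). In all, the interaction passed for 3418 genes, 1708 positive and 1710 negative.

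**Figure D2:**
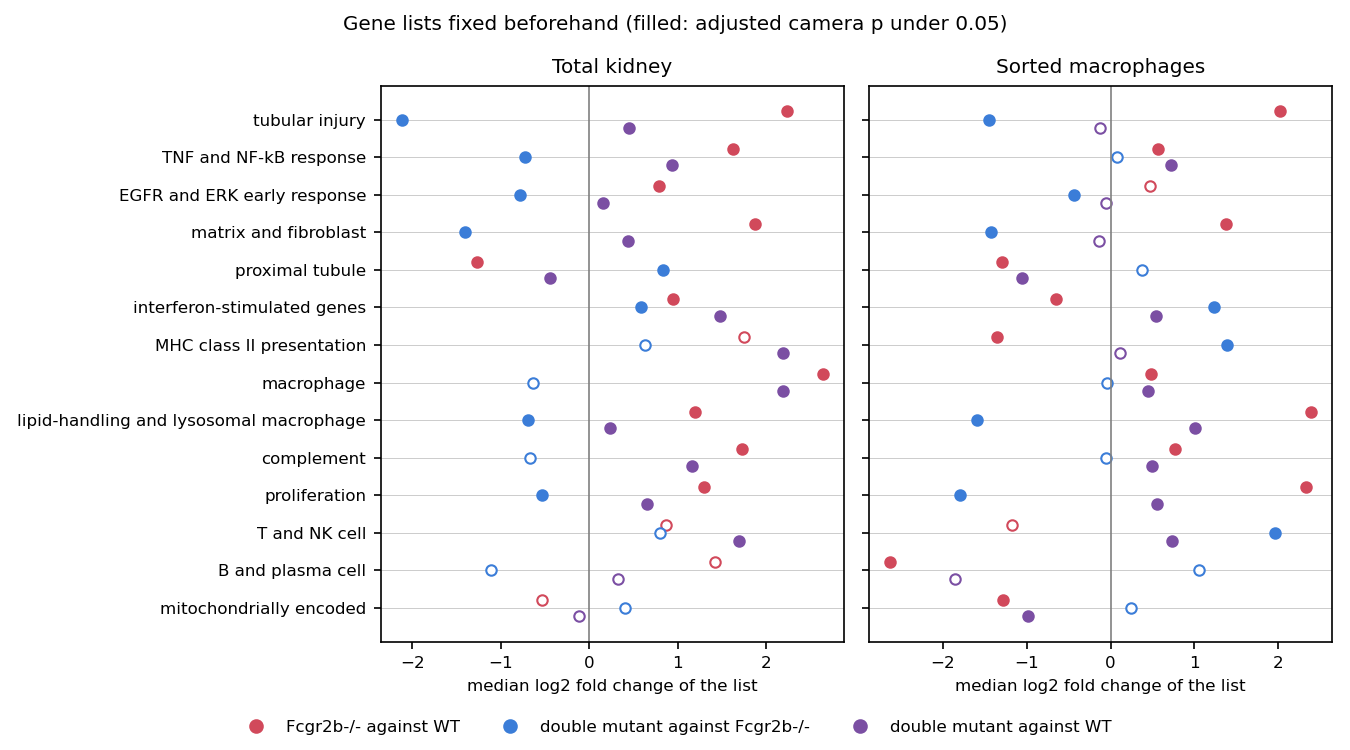
Median log2 fold change of the measured members of 14 gene lists, on the horizontal axis, for 3 comparisons in kidney and in sorted macrophages, with filled symbols where the adjusted camera p passed 0.05. In kidney the tubular injury list lay at 2.24 in Fcgr2b-/- against wild-type and at -2.12 in double-mutant against Fcgr2b-/-, and the interferon list at 0.95 and 0.59.

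Of 5055 kidney genes called in both Fcgr2b-/- against wild-type and double-mutant against Fcgr2b-/-, 5048 (99.9%) had opposite signs. The shared Fcgr2b-/- libraries favour opposite signs, and genes called in both were not simulated. Among genes picked by the first comparison alone 96.9% were opposite, against 86.6% simulated without effects (p below 0.05). The covariance of the fold changes was -0.358 against -0.0187 simulated. Independent lists would share 827 genes up then down and 853 down then up, where 2475 and 2573 were observed. With different pairs of Fcgr2b-/- libraries in each comparison the opposite share was 95.7 to 99.8%. Of the 7422 genes called in Fcgr2b-/- kidney 788 were also called with the same sign in double-mutant against wild-type kidney and 6629 were not called there.

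In sorted kidney macrophages, Fcgr2b-/- mice were compared with wild-type to find which transcripts of these cells accompany nephritis. Gpnmb averaged 1347 ± 1300 CPM (SD, n = 3) in Fcgr2b-/- macrophages against 0.919 ± 0.704 in wild-type, a log2 change of 9.09 ± 0.99 (SE). Trem2, a receptor for lipids, rose by 4.61 ± 0.34 from 25.9 ± 3.11 to 670 ± 184 CPM, and fibronectin, Fn1, by 7.30 ± 0.83. Il1rn, which encodes the IL-1 receptor antagonist, rose by 7.20 ± 0.45, the fatty acid binding protein Fabp5 by 6.65 ± 0.80 and Clec4e, a receptor for damaged cells and microbial glycolipid, by 6.39 ± 0.73. Ifi202b, an interferon-inducible gene, rose by 7.07 ± 0.16 (limma adjusted p = 1.05e-10), to 169 ± 24.1 CPM, and Pydc4, also interferon-inducible, changed by -6.74 ± 0.40. Ifi202b and Pydc4 lie 3 and 2.61 Mb from Fcgr2b. H2-Ab1 changed by -3.30 ± 0.41, from 14720 ± 1790 to 1570 ± 659 CPM, and Clec9a, a receptor of cross-presenting dendritic cells, by -3.62 ± 0.48.

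**Figure D3:**
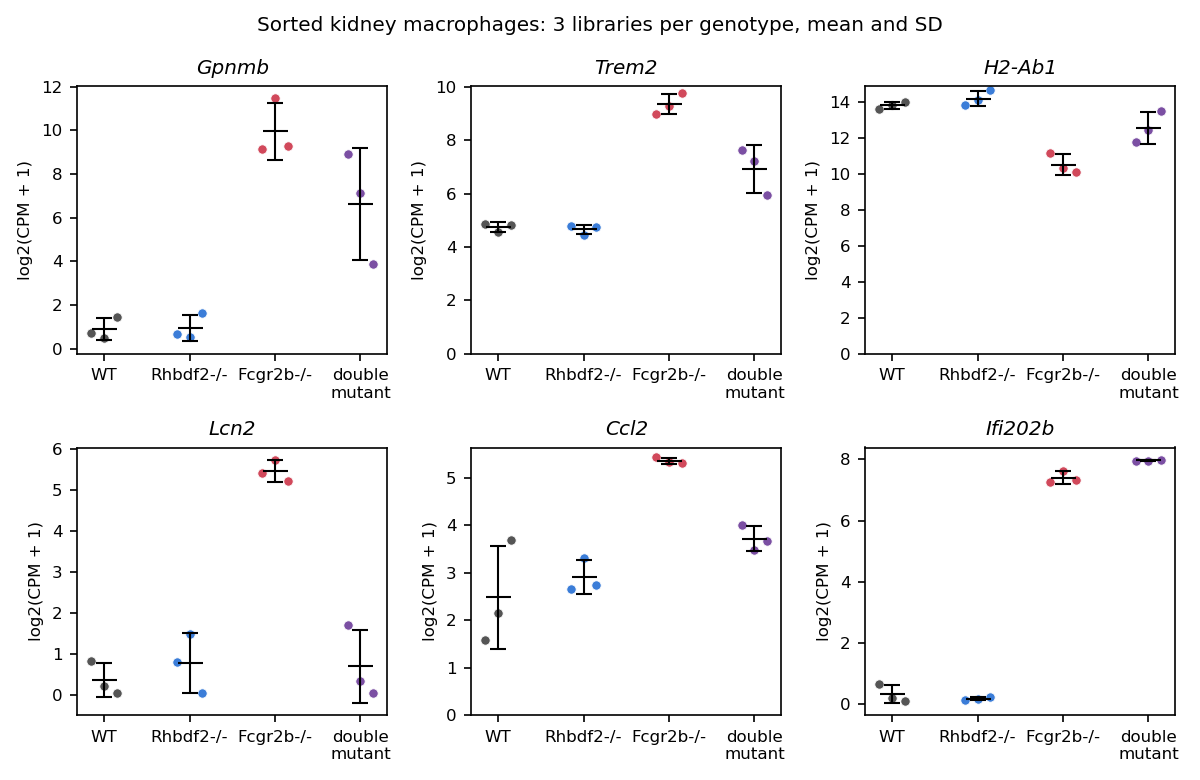
Expression of 6 genes in sorted kidney macrophages as log2(CPM+1), with 1 point per library, the 4 genotypes on the horizontal axis, and bars at the mean with its SD (n = 3). Gpnmb, Trem2, Lcn2 and Ccl2 were highest in Fcgr2b-/- libraries, H2-Ab1 was lowest there, and Ifi202b averaged 169 CPM in Fcgr2b-/- and 248 CPM in double-mutant libraries against 0.282 CPM in wild-type.

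The lipid and lysosomal macrophage list rose in 17 of 18 members in Fcgr2b-/- macrophages (17 rises and 1 fall over the list alone, median 2.39, camera adjusted p = 3.44e-09, adjusted p = 0.0633 with an estimated correlation). Proliferation genes rose in 21 of 22 cases (21 over the list alone, median 2.33, camera adjusted p = 2.32e-09, adjusted p = 0.433 with an estimated correlation). The mitotic kinase Cdk1 stood at 3.05 ± 0.32 and its partner Ccnb1 at 3.59 ± 0.36. Monocyte genes rose in 6 of 9 cases (6 over the list alone, median 3.00, camera adjusted p = 0.0056, adjusted p = 0.433 with an estimated correlation), and that test passed whichever library was left out. TNF and NF-kB response genes rose in 11 of 27 cases and fell in 3 (the same counts over the list alone, median 0.57, camera adjusted p = 0.00575, adjusted p = 0.433 with an estimated correlation). Members included Lcn2 at 5.09 ± 0.45, Cxcl1 at 5.05 ± 0.47 and the monocyte chemokine Ccl2 at 2.89 ± 0.41 (SE, n = 3 per group; limma adjusted p = 0.000154). MHC class II genes fell in 9 of 10 cases (10 over the list alone, median -1.35, camera adjusted p = 0.000607, adjusted p = 0.433 with an estimated correlation). Interferon-stimulated genes fell in 10 of 30 cases and rose in 0 (10 over the list alone, median -0.65, camera adjusted p = 0.00557, adjusted p = 0.632 with an estimated correlation). Among these were Stat2, a signal transducer of type I interferon, at -2.08 ± 0.29 and the RNA sensor Oas2 at -1.76 ± 0.25. The interferon list mean was 6.21, 6.28 and 5.23 in FcR2bko_847, FcR2bko_595 and FcR2bko_875 against 6.27, 6.45 and 7.30 in WTa, WTb and WT2. That list test did not pass without WT2 (0.101) or FcR2bko_875 (0.0771). Dendritic cell genes fell in 7 of 10 cases and rose in 1 (8 falls and 1 rise over the list alone, median -1.40, camera adjusted p = 0.0248, adjusted p = 0.433 with an estimated correlation), and their test did not pass without WT2 (0.078) or FcR2bko_875 (0.0524). Macrophage markers rose in 11 of 20 cases and fell in 2 (11 and 3 over the list alone, median 0.48, camera adjusted p = 0.0315, adjusted p = 0.545 with an estimated correlation), and their test did not pass without WTa (0.0787), WTb (0.0534) or FcR2bko_875 (0.0524).

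Handling stress genes rose in 7 of 19 cases and fell in 1 in Fcgr2b-/- against wild-type macrophages (the same counts over the list alone, median 0.37, camera adjusted p = 0.142). Their mean stood at 6.84 in WT2 and 6.71 in Rhbdf2-/- library iR2ko_KO3, against 5.12 to 5.37 in the other wild-type and Rhbdf2-/- libraries and 6.45 to 6.57 in Fcgr2b-/- libraries. Without WT2 12 rose (12 over the list alone, camera adjusted p = 0.00569). WT2 also differed from WTa and WTb for the TNF list (5.37 against 4.65 and 4.66) and the mitochondrial list (7.71 against 9.06 and 8.66). Transcripts of B cells and tubule cells moved with these groups. B and plasma cell genes fell in 8 of 11 cases and rose in 2 (9 falls and 2 rises over the list alone, median -2.63, camera adjusted p = 0.0248, adjusted p = 0.433 with an estimated correlation). Immunoglobulin kappa, Igkc, stood at -6.36 ± 0.84. Loop of Henle and distal tubule genes fell in 11 of 12 cases and rose in 1 (the same counts over the list alone, median -2.13, camera adjusted p = 0.00557, adjusted p = 0.433 with an estimated correlation). Proximal tubule genes fell in 13 of 21 cases and rose in 1 (the same counts over the list alone, median -1.30, camera adjusted p = 0.0248, adjusted p = 0.632 with an estimated correlation), and their test did not pass without WTa (0.103), FcR2bko_595 (0.0666) or FcR2bko_875 (0.124), where 4, 6 and 4 fell (1, 4 and 3 over the list alone). Umod, a glycoprotein of the thick ascending limb, averaged 2960 ± 1830 CPM (SD, n = 3) in wild-type macrophage libraries, 1940 ± 138 in Rhbdf2-/-, 487 ± 234 in Fcgr2b-/- and 695 ± 736 in double mutants. Genes of the tubular injury list rose in 11 of 15 cases and fell in 1 (the same counts over the list alone, median 2.02, camera adjusted p = 0.000607, adjusted p = 0.0832 with an estimated correlation). Genes encoded in mitochondria fell in 10 of 12 cases (12 over the list alone, median -1.28, camera adjusted p = 0.00189, adjusted p = 0.505 with an estimated correlation). The mitochondrial share of reads was 1.23 to 3.96% in wild-type and 0.721 to 1.06% in Fcgr2b-/- libraries.

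Of the pathway genes in macrophages, Adam17 rose by 0.86 ± 0.12 (SE, n = 3 per group; limma adjusted p = 0.000138), from 218 ± 24.1 to 397 ± 51.5 CPM (SD), and Rhbdf2 by 0.63 ± 0.21 (adjusted p = 0.0248). Fcgr2b changed by -0.96 ± 0.16 (adjusted p = 0.000493). Tnf had a log2 change of 0.52 ± 0.33 (adjusted p = 0.203) and Egfr of -0.66 (adjusted p = 0.16), and Hbegf was not listed in the macrophage table. Of the iRhom2 and ADAM17 list 7 genes rose and 7 fell among 20 (the same counts over the list alone, median -0.26, camera adjusted p = 0.878). In total 5551 of 10523 genes changed, 2547 higher and 3004 lower, while median-of-ratios scaling gave 2826 and 2750 and the genes at least as high as in wild-type kidney 1538 and 1285. The authors' deposited table gave 5455, with 5369 shared.

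The double-mutant macrophages were then compared with Fcgr2b-/- macrophages. Lcn2 averaged 0.853 ± 1.23 CPM (SD, n = 3) in double mutants against 43.3 ± 8.16, a log2 change of -4.76 ± 0.45 (SE; limma adjusted p = 8.36e-05). Fn1 changed by -4.56 ± 0.83, Spp1, which encodes osteopontin, by -4.29 ± 0.54, the chemokine receptor Ccr1 by -3.88 ± 0.58, Arg1, an arginine-degrading enzyme, by -3.72 ± 0.37, Trem2 by -2.42 ± 0.34, Gpnmb by -3.34 ± 0.99 and Ccl2 by -1.65 ± 0.41 (adjusted p = 0.0108). Clec9a rose by 4.40 ± 0.48, Xcr1, a chemokine receptor of dendritic cells, by 4.03 ± 0.66 and the secreted nuclease Dnase1l3 by 3.98 ± 0.47. Adam17 (0.07; adjusted p = 0.691), Tnf (-0.37; adjusted p = 0.442) and Rhbdf2 (-0.54; adjusted p = 0.0743) did not pass.

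Interferon-stimulated genes rose in 27 of 30 cases in double-mutant against Fcgr2b-/- macrophages (29 over the list alone, median 1.23, camera adjusted p = 4.4e-11, adjusted p = 0.327 with an estimated correlation). Ifi44 stood at 2.57 ± 0.43 and Stat2 at 1.74 ± 0.29. MHC class II genes rose in 9 of 10 cases (10 over the list alone, median 1.39, camera adjusted p = 5.89e-06, adjusted p = 0.281 with an estimated correlation). T and NK cell genes rose in 12 of 18 cases (14 rises and 1 fall over the list alone, median 1.96, camera adjusted p = 0.000374, adjusted p = 0.626 with an estimated correlation). Their mean was 5.33 and 4.60 in iR2ko_579 and iR2ko_823 but 3.01 in iR2ko_592, within the Fcgr2b-/- range of 2.30 to 3.09. Called T and NK members numbered 16 without iR2ko_592 (16 over the list alone), but 1 without FcR2bko_595 (11), 2 without FcR2bko_875 (2), 2 rises and 1 fall without iR2ko_579 (1 and 1) and 3 without iR2ko_823 (2), and the list test passed each time. Dendritic cell genes rose in 6 of 10 cases (6 over the list alone, median 0.99, camera adjusted p = 0.00326, adjusted p = 0.176 with an estimated correlation). The lipid and lysosomal list fell in 14 of 18 members (16 falls and 1 rise over the list alone, median -1.59, camera adjusted p = 3.74e-07, adjusted p = 0.0472 with an estimated correlation). Proliferation genes fell in 21 of 22 cases (22 over the list alone, median -1.80, camera adjusted p = 4.4e-11, adjusted p = 0.28 with an estimated correlation). The TNF and NF-kB list went both ways, with 6 rises and 9 falls among 27 (the same counts over the list alone, median 0.08, camera adjusted p = 0.524), and its median and its test differed in sign. A total of 3113 genes changed, 1663 higher and 1450 lower, and median-of-ratios scaling gave 1409 and 1733. The authors' deposited table gave 3017, with 2930 shared.

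Rhbdf2-/- and wild-type macrophages differed in 2 genes, both higher. St6galnac1, a sialyltransferase, averaged 30.8 ± 1.71 CPM (SD, n = 3) against 0.0578 ± 0.048, a log2 change of 4.91 ± 0.39 (SE; limma adjusted p = 0.000284), and Gm11735, a predicted gene, averaged 5.8 ± 0.751 CPM (adjusted p = 0.00243). Gm11735 had 0 reads in each wild-type library, so it was at least 63.9-fold higher in Rhbdf2-/- macrophages, against the floor of 3 reads per library. Both lie beside Rhbdf2 on chromosome 11, St6galnac1 at 0.158 Mb and Gm11735 at 0.132 Mb. At an unadjusted p below 0.05 there were 339 genes where 526 would be expected by chance. Voom on recovered reads gave 0 genes with 347 at an unadjusted p below 0.05, the 2 groups alone gave 5, and the authors' deposited table gave 0 with a smallest FDR of 0.102. Among other genes near Rhbdf2, St6galnac2 had a log2 change of 4.09 ± 0.60 (adjusted p = 0.0645), BC018473 of 8.86 ± 1.54 (adjusted p = 0.115) and the splicing factor Srsf2 of -1.29 ± 0.21 (adjusted p = 0.109). Proximal tubule genes had a median of 0.65 (camera adjusted p = 5.11e-06). T and NK cell genes had a median of 0.47 (camera adjusted p = 0.00561) and distal tubule and loop genes a median of -0.40 (camera adjusted p = 0.00561, all 3 adjusted p = 0.947 with an estimated correlation). In each of these 3 lists 0 members passed the threshold and 0 over the list alone. The proximal tubule test did not pass without iR2ko_KO3 (0.0555), the T and NK test without iR2ko_KOb (0.844), WTa (0.187) or WTb (0.135), and the loop test without WTa (0.187) or WTb (0.109). Rhbdf2 itself had a log2 change of -0.49 ± 0.21 (adjusted p = 1).

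**Figure D4:**
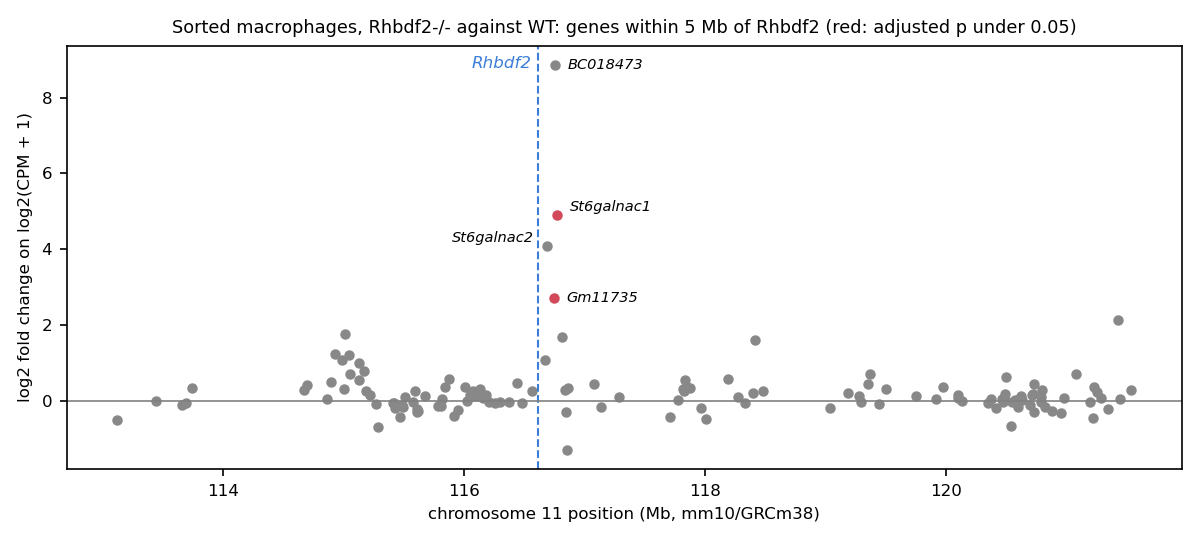
Log2 fold change in Rhbdf2-/- against wild-type macrophages (vertical axis) for genes within 5 Mb of Rhbdf2, by position on chromosome 11 in Mb (horizontal axis), with 1 point per gene. St6galnac1 (4.91), St6galnac2 (4.09) and BC018473 (8.86) lay above the other genes and Srsf2 (-1.29) below them.

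Double-mutant macrophages were compared with Rhbdf2-/- macrophages for the effect of Fcgr2b loss without iRhom2. Ifi202b rose by 7.77 ± 0.16 (SE, n = 3 per group), Gpnmb by 5.69 ± 0.99, Cd300e, an activating receptor of myeloid cells, by 5.23 ± 0.58, complement C3 by 2.85 ± 0.38 and Adam17 by 0.89 ± 0.12 (limma adjusted p = 0.00137). Pydc4, near Fcgr2b like Ifi202b, changed by -4.95 ± 0.40, the immunoglobulin alpha chain Igha by -4.22 ± 1.08 and the joining chain Igj by -3.56 ± 0.99. Egfr changed by -1.31 ± 0.38 (adjusted p = 0.0356), and Lcn2 stood at -0.08 (adjusted p = 0.917). The lipid and lysosomal list rose in 10 of 18 members (11 over the list alone, median 0.96, camera adjusted p = 7.79e-07, adjusted p = 0.135 with an estimated correlation). Proximal tubule genes fell in 14 of 21 cases (17 over the list alone, median -1.70, camera adjusted p = 7.79e-07), and genes encoded in mitochondria in 10 of 12 (12 over the list alone, median -1.06, camera adjusted p = 8.58e-06, both adjusted p = 0.697 with an estimated correlation). Interferon-stimulated genes rose in 3 of 30 cases (8 over the list alone, median 0.62, camera adjusted p = 9.49e-05, adjusted p = 0.855 with an estimated correlation), 0 without iR2ko_KO3 and 13 without FcR2bko_875 (0 and 18 over the list alone), and monocyte genes in 3 of 9 (3 over the list alone, median 1.21, camera adjusted p = 0.0144, adjusted p = 0.697 with an estimated correlation), the latter test not passing without iR2ko_579 (0.0542). Called proximal tubule members ranged from 1 to 15 and mitochondrial ones from 0 to 12 with single libraries left out, lowest without iR2ko_KOa (16 and 10 over the list alone). A total of 1918 genes changed, 968 higher and 950 lower, while the genes at least as high as in wild-type kidney gave 835 higher and 231 lower. The count was 598 to 2601 when single libraries were left out, 598 without iR2ko_579.

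Against wild-type, double-mutant macrophages retained differences in part of these genes. Ifi202b was higher by 7.62 ± 0.16 (SE, n = 3 per group), Cd300e by 5.94 ± 0.58, Il1rn by 5.80 ± 0.45, the chemokine Ccl8 by 3.79 ± 0.48 and Adam17 by 0.93 ± 0.12. Pydc4 changed by -5.08 ± 0.40, Igha by -4.42 ± 1.08 and Igj by -3.80 ± 0.99. Ccl2 had a log2 change of 1.24 ± 0.41 (limma adjusted p = 0.0554) and Lcn2 of 0.33 (adjusted p = 0.635). The lipid and lysosomal list rose in 11 of 18 members (12 over the list alone, median 1.01, camera adjusted p = 7.12e-07, adjusted p = 0.131 with an estimated correlation). TNF and NF-kB response genes rose in 6 of 27 cases (9 over the list alone, median 0.72, camera adjusted p = 0.000538). Distal tubule and loop genes fell in 8 of 12 cases (9 falls and 1 rise over the list alone, median -1.98, camera adjusted p = 0.000727, both adjusted p = 0.602 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 12 cases (12 over the list alone, median -0.98, camera adjusted p = 2.9e-05). Genes of the EGFR ligand and receptor list fell in 3 of 6 cases (4 over the list alone, median -1.09, camera adjusted p = 0.00793, both adjusted p = 0.602 with an estimated correlation). The 6 measured were the receptors Egfr and Erbb2 to Erbb4, the inhibitor Errfi1 and 1 ligand, Egf. Egf averaged 880 ± 507 CPM (SD, n = 3) in wild-type and 173 ± 158 in double-mutant libraries. Tubule RNA may add to these falls and to the Egfr fall above. Interferon-stimulated genes, which fell in Fcgr2b-/- against wild-type, rose in 3 of 30 cases (3 over the list alone, median 0.54, camera adjusted p = 0.000333, adjusted p = 0.799 with an estimated correlation), 0 without WTa and 18 without WT2 (0 and 22 over the list alone). Monocyte genes rose in 3 of 9 (3 over the list alone, median 1.43, camera adjusted p = 0.00731, adjusted p = 0.602 with an estimated correlation), 1 without WTa and 5 without WT2 (2 and 6 over the list alone). Both tests passed whichever library was left out. With single libraries left out, called members ranged from 1 (WTb) to 15 (WT2) for the TNF list, 0 (WTa) to 9 (iR2ko_823) for the loop list, 0 (WTa) to 12 (WT2) for the mitochondrial list and 0 (WTa) to 5 (WT2) for the EGFR list, the lowest being 1, 8, 8 and 2 over the list alone. In total 1943 genes changed, 1040 higher and 903 lower, while the genes at least as high as in wild-type kidney gave 867 and 203. The authors' deposited table gave 1547, with 1514 shared. The 2 groups alone gave 599, 427 higher and 172 lower, and leaving out single libraries gave 450 to 3007, 450 without WTb and 3007 without WT2.

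The interaction in macrophages passed for 1255 genes, 635 positive and 620 negative, and median-of-ratios scaling gave 543 and 717. The effect of Rhbdf2 loss on Lcn2 was lower by -5.18 ± 0.64 (SE, n = 3 per group; limma adjusted p = 0.0025) without Fcgr2b than with it, on Spp1 by -4.48 ± 0.76, on Ccr1 by -4.40 ± 0.83 and on Ccl2 by -2.08 ± 0.58 (adjusted p = 0.0385), while it was higher on Clec9a by 4.02 ± 0.67. Adam17 had an interaction of 0.03 (adjusted p = 0.949). Interferon-stimulated genes had a positive interaction in 11 of 30 cases (25 over the list alone, median 1.30, camera adjusted p = 6.53e-11, adjusted p = 0.333 with an estimated correlation). Proliferation genes had a negative interaction in 11 of 22 cases (18 over the list alone, median -2.04, camera adjusted p = 3.31e-11, adjusted p = 0.302 with an estimated correlation). The lipid and lysosomal list had a negative interaction in 7 of 18 members (13 over the list alone, median -1.44, camera adjusted p = 1.19e-06, adjusted p = 0.0612 with an estimated correlation). Without iR2ko_KOa called members of these lists numbered 2, 7 and 4 (18, 14 and 10 over the list alone). Interferon members numbered 3 without iR2ko_KO3 or iR2ko_592 and 4 without iR2ko_KOb (15, 20 and 21 over the list alone), and proliferation members 17 without iR2ko_KO3 (21). Each of the 3 tests passed whichever library was left out. Positive interactions were also found for MHC class II genes in 3 of 10 cases (7 over the list alone, median 1.24, camera adjusted p = 0.000115, adjusted p = 0.333 with an estimated correlation) and dendritic cell genes in 2 of 10 (2 over the list alone, median 0.76, camera adjusted p = 0.0147, adjusted p = 0.264 with an estimated correlation). T and NK cell genes had 1 in 18 (1 over the list alone, median 1.43, camera adjusted p = 0.0189, adjusted p = 0.747 with an estimated correlation), and their test did not pass in 6 of 12 fits with a library left out (0.196 without iR2ko_579, but 1.39e-05 without iR2ko_592). The count ranged from 517 to 1304 when single libraries were left out, 517 without iR2ko_KOa.

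Of 2637 macrophage genes called in both Fcgr2b-/- against wild-type and double-mutant against Fcgr2b-/-, 2619 (99.3%) had opposite signs. Among genes called in the first 92.9% did, against 85.8% of simulated genes at an unadjusted p below 0.05. These thresholds differ too, and the shares were not tested against each other. The covariance was -0.542 against -0.042 simulated. Independent lists would share 350.96 genes up then down and 475 down then up, where 1278 and 1341 were observed. With 3 Fcgr2b-/- libraries these could not be split, so part of the excess may come from the shared libraries. Of the 5551 genes called in Fcgr2b-/- macrophages 1628 were also called with the same sign in double-mutant against wild-type macrophages and 3905 were not called there.

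Changes were compared between the tissues over the 9884 genes measured in both. In Fcgr2b-/- against wild-type 3124 genes were called in both tissues where 3090 would be by chance (Fisher's exact test, two-sided p = 0.168), and 66% of them moved in the same direction. For double-mutant against wild-type 215 genes were shared against 142 by chance (Fisher's exact p = 1.99e-11), with 93.5% in the same direction, and for double-mutant against Rhbdf2-/- 108 against 68.3 (Fisher's exact p = 3.65e-07). For double-mutant against Fcgr2b-/- there were 1178 against 1220 (Fisher's exact p = 0.0556). For the interaction it was 322 against 293 (Fisher's exact p = 0.0359, but 0.891 at an FDR of 0.1). Genes are not independent replicates, and library kits differed by tissue.

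Genes near the targeted loci were counted because DNA next to a targeted gene can stay with it through breeding. In double-mutant against Rhbdf2-/- macrophages 47 of 124 genes within 10 Mb of Fcgr2b changed (37.9%) against 18% elsewhere (Fisher's exact p = 2.21e-07), and in kidney 15 of 128 (11.7%) against 3.41% (Fisher's exact p = 4.02e-05). In double-mutant against wild-type macrophages 33.1% of genes near Fcgr2b changed against 18.3% elsewhere (Fisher's exact p = 9.53e-05), and 31.5% of those near Rhbdf2 against 18.3% (Fisher's exact p = 4.4e-05). In Fcgr2b-/- against wild-type the shares near Fcgr2b were 60.9% against 60.3% in kidney (Fisher's exact p = 0.928) and 57.3% against 52.7% in macrophages (Fisher's exact p = 0.321). Nearby Ifi202b was 1.07 to 2.02 CPM in every kidney library with intact Fcgr2b and 6.43 to 19.6 in all others.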

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

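The test for single libraries far from their group was run on 81 kidney genes, part of them chosen after their values had been seen, and on 25 gene lists fixed beforehand, and the interaction tests were planned. In groups of 4 kidney libraries, the gap of the highest or lowest library to its neighbour was divided by the range of the group. Of 424 such tests 20 (4.72%) passed the 95% limit, and chance flags about 1 in 20 groups.

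Double-mutant library iR2ko_65 stood apart for Ltbp2 (gap of 0.92 of the range), Slc22a7 (0.851), Cmpk2 (0.911), Ifit1 (0.834) and Frmd8 (0.906). It also stood apart for the iRhom2 and ADAM17 list (0.848), the TNF and NF-kB list (0.839) and the mitochondrially encoded list (0.859), lower than the other double mutants in each but the last. Wild-type library WT_356 stood apart for Krt8 (0.843), Cxcl1 (0.833), Fos (0.91) and the endothelium list (0.931), higher in each. The other wild-type libraries were Gatm in WT_346 (0.926), Myc in WT_550 (0.879) and Acta2 in WT_388 (0.842). In Rhbdf2-/- kidney, Lcn2 stood apart in iR2ko_355 (0.949), at 15.5 CPM against 2.31 to 2.59, and Slc22a7 (0.862) and Gbp3 (0.85) in iR2ko_351. Lox stood apart in Fcgr2b-/- library FcR2bko_594 (0.8295) and Krt19 in double-mutant library iR2ko_348 (0.854).

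The effect of Rhbdf2 loss differed with and without Fcgr2b in kidney for Rhbdf2 by -0.90 (limma adjusted p = 0.0136), Hbegf by -1.33 (adjusted p = 0.00142), Havcr1 by -4.11 (adjusted p = 0.0081) and Lcn2 by -4.95 (adjusted p = 0.00123). In macrophages it differed for Lcn2 by -5.18 (adjusted p = 0.0025) and Ccl2 by -2.08 (adjusted p = 0.0385).

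Several lists moved up in every Fcgr2b-/- kidney library and down in every Fcgr2b-/- macrophage library against the wild-type mean. These differences between the tissues were not tested. The kidney value exceeded the macrophage value by 1.09 for the iRhom2 and ADAM17 list (0.93 and -0.17), by 1.55 for interferon-stimulated genes (0.79 and -0.77) and by 3.17 for MHC class II genes (1.44 and -1.73). For dendritic cell genes the difference was 2.02 (0.68 and -1.34), for T and NK cell genes 1.81 (0.94 and -0.87) and for genes near Fcgr2b on chromosome 1 it was 0.81 (0.60 and -0.21).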

How the results depend on the processing

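Voom on recovered reads, the deposited values without a pseudocount, and macrophage genes at least as high as in wild-type kidney were chosen after the data had been seen, as was the filter value of 5, and the other alternatives were planned. The planned count-based alternatives (other normalization factors within a count fit, a second count tool and a count filter) were not run because the deposited values are log2 CPM, and median-of-ratios scaling was applied to CPM in their place. No scaling alternative moved the median of all genes by 0.1 or more. For named genes 18338 of 20109 alternative values kept their side of the threshold, 1547 lost the call and 224 gained it. Among called values 0 changed sign.

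Counts of called genes moved by more than 1.5 times in the following cases. With the 2 compared groups alone the count was 3550 for double-mutant against Fcgr2b-/- kidney, 5 for Rhbdf2-/- against wild-type macrophages and 599 for double-mutant against wild-type macrophages, where fewer libraries estimate the spread. With voom on recovered reads it was 77 for double-mutant against Rhbdf2-/- kidney, 479 for double-mutant against wild-type kidney and 0 for Rhbdf2-/- against wild-type macrophages (347 at an unadjusted p below 0.05), and the cause was not tested. For Rhbdf2-/- against wild-type macrophages it was 1 with a mean CPM of at least 5, where fewer genes were tested, and 1 with the deposited log2 values. Among the 4628 macrophage genes at least as high as in wild-type kidney, where fewer genes were tested, it was 2823 for Fcgr2b-/- against wild-type, 1992 for double-mutant against Fcgr2b-/-, 1066 for double-mutant against Rhbdf2-/- and 1070 for double-mutant against wild-type.

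The letters a and b are shared by wild-type and Rhbdf2-/- macrophage titles, and nothing in the labels says that they mark a day or litter. The correlation of deviations was 0.242 for a and -0.054 for b. A replicate block gave 162 genes for double-mutant against Rhbdf2-/- (122 higher, 40 lower), 253 for double-mutant against wild-type (200 higher, 53 lower), 4103 for Fcgr2b-/- against wild-type, 2926 for double-mutant against Fcgr2b-/-, 2 for Rhbdf2-/- against wild-type and 1054 for the interaction.

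Leaving out single libraries gave 6613 to 7660 genes for Fcgr2b-/- against wild-type kidney, 4855 to 5902 for double-mutant against Fcgr2b-/- kidney, 0 for Rhbdf2-/- against wild-type kidney in each limma fit, and 2738 to 3951 for the kidney interaction. For double-mutant against Rhbdf2-/- kidney the range was 27 to 1566. The counts were 178, 199, 169 and 177 without WT_346, WT_356, WT_388 and WT_550, then 35, 27, 51 and 256 without iR2ko_334, iR2ko_351, iR2ko_352 and iR2ko_355, then 1060 without FcR2bko_594, and 71, 27, 31 and 1566 without iR2ko_348, iR2ko_370, iR2ko_367 and iR2ko_65. For double-mutant against wild-type kidney the range was 121 to 1706, with 121, 557, 381 and 155 without the wild-type libraries in the same order, 589 without iR2ko_352, and 417, 185, 190 and 1706 without the double mutants in the same order.

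In macrophages, where a group then keeps 2 libraries, the range was 4583 to 5672 for Fcgr2b-/- against wild-type and 2217 to 3456 for double-mutant against Fcgr2b-/-. For Rhbdf2-/- against wild-type it was 2 to 8, with 8 without FcR2bko_847. For double-mutant against Rhbdf2-/- it was 598 to 2601, with 667, 880 and 632 without iR2ko_KOa, iR2ko_KOb and iR2ko_KO3, 598 without iR2ko_579 and 2601 without WT2. For double-mutant against wild-type it was 450 to 3007, with 537, 450 and 3007 without WTa, WTb and WT2 and 715 without iR2ko_579. For the interaction it was 517 to 1304, with 647 without WTb, 517 and 695 without iR2ko_KOa and iR2ko_KOb, 788 without FcR2bko_595 and 705 without iR2ko_592. The cause of these moves was not tested.

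Of 306 list tests 138 passed, against 4 with an estimated correlation (134 lost) and 124 with members of several lists left out (15 lost). Leaving out single libraries, an alternative added for lists after the data had been seen, ended the call at least once for 12 of 72 passing tests in kidney and 21 of 66 in macrophages, and 29 of 78 and 28 of 90 others gained it. The tissues shared 634 interaction genes at an FDR of 0.1 in place of 322 (Fisher's exact p = 0.891). Near Fcgr2b in Fcgr2b-/- against wild-type macrophages 67.1% of genes were called within 5 Mb (Fisher's exact p = 0.0162) in place of 57.3% within 10 Mb, and near Rhbdf2 in double-mutant against Fcgr2b-/- macrophages 37.7% within 20 Mb (Fisher's exact p = 0.0025) in place of 35.2%. The cause was not tested. Depth limits low genes most, since 3 reads lie at up to 0.106 CPM in kidney.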

Other observations

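The tests of explanations below were chosen after the patterns had been seen and the bounds for the counts of other splits were written after the results, while the gene list tests were planned. In double-mutant against Fcgr2b-/- macrophages, tubular injury list genes fell in 10 of 15 cases (11 adjusted over the list alone, median -1.45, camera adjusted p = 9.12e-07, adjusted p = 0.0298 with an estimated correlation). Matrix genes fell there in 8 of 11 cases (8 adjusted over the list alone, median -1.42, camera adjusted p = 0.000691, adjusted p = 0.0472 with an estimated correlation). The injury list also had a negative interaction in 6 of 15 genes (9 adjusted over the list alone, median -1.08, camera adjusted p = 9.12e-07, adjusted p = 0.028 with an estimated correlation). Alternative macrophage genes fell in 4 of 10 cases and rose in 1 (the same counts adjusted over the list alone, median -1.05, camera adjusted p = 0.0114, adjusted p = 0.327 with an estimated correlation), and that test did not pass without iR2ko_592 (0.0548).

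In Fcgr2b-/- kidney, monocyte genes rose in 8 of 11 cases and fell in 1 (the same counts adjusted over the list alone, median 1.8, camera adjusted p = 0.00626, adjusted p = 0.42 with an estimated correlation).

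Kidney genes with higher levels in female mice were low in Fcgr2b-/- kidney, with log2 changes of -4.29 for Slc22a7, -4.17 for Slc22a19, -2.95 for Prlr and -2.67 for Slc7a12, while Cyp4a14 stood at 0.08. Male animals are argued against by Xist, at 6.95 CPM or more in every Fcgr2b-/- kidney, with 0 of 4 Y-linked genes listed. Loss of proximal tubule cells, even or of a single segment (untested), stays open. The female list's median lay -1.67 from that of 18 other proximal tubule genes (median -1.28, SD 0.54), but the list was chosen after its values were seen. A shift towards male-type expression cannot be told apart, with 3 male-biased genes called higher and 2 lower of 8, Cyp2j13 at 3.39 and Kap at -4.85. Sequencing lane cannot be told apart either, with 1 lane per group, and nephritis itself may be the source.

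Genes beside Rhbdf2 differed between libraries. The 9 genes within 10 Mb of Rhbdf2 with p below 0.001 in Rhbdf2-/- against wild-type macrophages were scaled in log2(CPM+1). The wild-type mean was 0% and the Rhbdf2-/- mean 100%. Medians were 30.9% in FcR2bko_595 (10% in CPM), 28.3% in FcR2bko_875 (-26.4 to 92.1%, 8.34% in CPM) and -3.4% in FcR2bko_847 (-50.4 to 88.4%). In double mutants they were 60.7, 74 and 94.2%. In FcR2bko_595 St6galnac1, St6galnac2, Gm11735 and BC018473 lay at 40.2, 52.4, 30.9 and 86%. Mxra7, Gm11709, Cd300lh and Cd300ld lay at -20.3, -25.5, -2.56 and -60% and Srsf2 at 135%. Thus 1 targeted Rhbdf2 copy in some Fcgr2b-/- libraries cannot be told from other effects. DNA of another strain or another effect in cis of the targeted allele may contribute, since genes with p below 0.001 lay within 10 Mb of Rhbdf2 more often than others (9 of 15, Fisher's exact p = 2.13e-13). Tubule RNA carried over is argued against for St6galnac2, which stood in Rhbdf2-/- macrophages at 129% of its kidney level, against 33.2% for Umod.

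Tubule genes were lower in Fcgr2b-/- macrophages than in wild-type. Carry-over of tubule RNA into the sorted cells may account for their presence, since the levels of 33 tubule genes in wild-type macrophages followed those in wild-type kidney (Spearman rho 0.636, Pearson r 0.625, permutation p = 1e-04 over genes, which are not independent replicates). The gate on CD45 would remove tubule cells but not free RNA. Whether carry-over made all the changes stays open. Fcgr2b-/- values helped pick the 4628 genes at least as high as in wild-type kidney (61% called). A change of the macrophages with disease stays open and untested.

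Other splits of the same libraries were counted for each comparison. In kidney chance can be excluded for Fcgr2b-/- against wild-type (1 of 35 splits as large, 7422 genes, highest other 266), double-mutant against Fcgr2b-/- (1 of 35, 5578, highest other 330) and double-mutant against wild-type (1 of 35, 898, highest other 29). For Rhbdf2-/- against wild-type the count says nothing of chance, since with 0 called genes by limma (272 at an unadjusted p below 0.05, 0 by voom) all 35 of 35 splits were as large from the outset (highest other 0). The count leaves chance open for double-mutant against Rhbdf2-/- (2 of 35, 431), where the split exchanging iR2ko_65 and iR2ko_355 called 859 genes. For the kidney interaction 3 of 100 drawn splits were as large (3418, highest other 3559). All 3 were among the 4 splits that kept Fcgr2b-/- and double-mutant libraries apart, so this count leaves chance open. In macrophages 10 splits are too few for a share under 0.05. There 1 split was as large for Fcgr2b-/- against wild-type (5551, highest other 0), double-mutant against Fcgr2b-/- (3113, highest other 0), Rhbdf2-/- against wild-type (2, highest other 1), double-mutant against Rhbdf2-/- (1918, highest other 1) and double-mutant against wild-type (1943, highest other 0). For the macrophage interaction 6 of 100 drawn splits were as large (1255, highest other 1514). All 6 were among the 10 that kept those groups apart, so this count leaves chance open too.

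With no explanation tested, kidney library FcR2bko_594 held BC018473 at 0.164 CPM against 13.6 to 16.7 in the other Fcgr2b-/- kidneys.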
